A study of Homo sapiens with 12 samples.

How the data were processed

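RNA of human U937 cells was measured on 12 Affymetrix oligonucleotide arrays. Per the protocol in the labels, the cells had been electroporated with a plasmid for GFP alone, for GFP with wild-type PML-RARA (PRWT) or for GFP with PR2VR, and GFP-positive cells had been sorted 6 h or 9 h later, per the labels. The titles of the PRWT and PR2VR samples count hours after infection and those of the GFP samples hours after transfection. Both were taken to mean the electroporation, but a difference in procedure would coincide with the comparison of fusion with GFP cells. This gives 6 groups of 2 arrays, 4 arrays per construct and 6 per time point. Each sample was placed in its group from its title, which also gives its replicate number. The labels do not say whether replicates came from separate transfections, so the p-values measure only the spread between these samples, which may be technical.

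Per the labels' protocols, total RNA was extracted with Trizol and made into biotin-labelled cRNA by the standard Affymetrix procedure. Per the submitters' processing notes, the deposited intensity values were computed with MAS5, whose version is not given in the sources used here. The deposited intensity is the MAS5 signal on a linear scale, from 0.5 to 289408.3, with 0 negative values. The mean signal of an array after trimming 2% at each end was 1500.2 on every array, so the authors' values were already scaled to a common level and were not normalized further. No detection calls were used here. The genome build and the scanner output were not used here.

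The table holds 54675 probe sets, of which 62 are controls. Of the other 54613 probe sets, 41091 have 1 gene symbol in the platform annotation, 1801 have several and 11721 are unnamed here. Entrez numbers of 41043 probe sets matched the GRCh38 RefSeq gene table, which changed 0 symbols. For each of 19775 genes the probe set with the highest mean log2 value was taken, from probe sets with 1 symbol only. Values were transformed as log2(signal + 62.5), where 62.5 is the 20th percentile of all values. Fold changes are on this scale, which understates changes of genes with low signal. Genes were tested where the mean over all arrays reached the 40th percentile of probe sets (log2 of 7.85, a signal of 168.9), which left 13959 genes. The 9 bacterial control probe sets, whose targets are absent from human RNA, had a median signal of 37.7 and ranged from 4.4 to 616. At most 0.0677% of probe sets had equal values on any 2 arrays, so no array was a copy of another.

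Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group, contrasts, and moderated variances that follow a trend on signal (6 residual degrees of freedom). All 12 arrays shared 1 estimate of the spread, because each group holds 2 arrays. Adjusted p is the Benjamini-Hochberg value over the 13959 genes, and a gene passed where it was under 0.05. Errors are standard errors (SE) of the log2 difference unless SD is written. There were 13 comparisons, of which 5 average over times or constructs. Each gene list (28 of them) was tested with limma's camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the arrays and with fry, with adjustment over lists within a comparison. The groups, comparisons, tests, lists, settings and the rule for naming genes were fixed before the data were examined. That rule takes, in each of the 5 averaged comparisons, the 10 largest changes per direction that passed with the same direction at both times (or in all 3 constructs). Where fewer than 5 passed in a direction it takes the 5 with the smallest unadjusted p, given as values. It adds up to 4 members per list with the smallest unadjusted p, 3 genes per direction in the other comparisons, and PML and RARA always. After the data were seen, the same rule was also applied to the fit with the block described next.

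Replicate numbers are shared by the constructs. The deviations of same-numbered arrays from their group means correlated across genes at r = 0.36, 0.15 and 0.21 between constructs at 6 h, and at r = 0.60, 0.63 and 0.56 at 9 h. All 6 are over 0.1. Same-numbered arrays of different times, however, correlated at r = -0.022 to 0.19. The numbers, which come from the titles, therefore clearly pair the arrays at 9 h. At 6 h the value of 0.15 lies within that range and 0.21 lies close to it, so pairing there is weakly shown. The 3 arrays of 1 time point and number are called a set below, and there are 4 sets. The fit without sets was fixed as the principal one. The fit with the set as a block (4 residual degrees of freedom) was planned as its alternative, and is given beside a result where the call or the count differs.

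The fits, the calls and camera were tested on simulated log2 values for the comparison of both fusions with GFP. The offset, the choice of probe sets and the filter were not part of this test. There were 13959 genes and 5 data sets in which 200 genes changed, and log2 changes of 2 and 3 were decreases only. The simulated arrays held the set effects and residual spread estimated by the fit with the block, so the gain from the block was built in. Without the block it recovered 3.0% of genes changed by a log2 of 1, 47.6% at 2 and 70.4% at 3, with 0 false calls. With the block it recovered 30.8%, 72.0% and 88.4%, with 24 false calls beside 555 true ones. With no gene changed, 0 genes were called by either fit, and 1 list passed over the 5 data sets. The simulated residuals were independent between genes. That list count therefore does not give the error rate of camera where members of a list vary together. The number of arrays limits the precision: the median SE of a log2 difference was 0.33 without and 0.24 with the block.

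Alternatives fixed in advance were an offset of 1, quantile normalization, no filter, all probe sets, moderated variances without the trend, the block, only the arrays of the groups compared, and leaving out each array in turn. Where an array left out leaves 1 array in a group, that array is assumed to vary like the others. Added after seeing the data were the omission of the 3 arrays of 9 h number 2, the set as a random block, and those alternatives applied to the fit with the block and to the lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.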

Results

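U937 cells, a human monocytic line from a histiocytic lymphoma, were made to express PML-RARA, the fusion of the PML and RARA genes found in acute promyelocytic leukemia. PRWT is the wild-type fusion. PR2VR is taken to be the protease-resistant form that the series is named for, although its sample labels call it wild type too, as they do PRWT. Cells with GFP alone were the control. Each construct was measured on 4 arrays, 2 from cells sorted 6 h and 2 from cells sorted 9 h after transfection. All 12 arrays had a trimmed mean signal of 1500.2, their median signal ran from 238.8 to 435.8, and between 58.2% and 71.7% of probe sets lay above a signal of 168.9.

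The transfected genes were measured first, since they check the labels. RARA, the retinoic acid receptor alpha gene, has 5 probe sets and PML, a nuclear body protein gene, has 10. The RARA probe set with the highest mean signal read between 48.2 and 309.2 on the 4 GFP arrays, between 11970.8 and 58985 on the PRWT arrays and between 9281.2 and 41097.2 on the PR2VR arrays. RARA rose by 7.72 ± 0.54 (log2, SE, n = 4 arrays per construct) in PRWT and by 7.32 ± 0.54 in PR2VR against GFP, with adjusted p of 3.5e-05 and 6.8e-05 in limma. The difference of PR2VR from PRWT was -0.40 ± 0.54 (adjusted p = 1.0). Within the 4 sets PR2VR differed from PRWT by -0.68, -0.36, -0.15 and -0.41 (SE of the mean 0.11), and an exact sign-flip permutation test, chosen after the values were seen, gave p = 0.125, the smallest that 4 sets allow. In the unpaired fit, where an omission breaks a pair, the sign turned to 0.17 when number 1 of PRWT at 6 h was left out and to 0.10 without number 2 of PR2VR at 6 h. On the GFP arrays this probe set lay within the range of the bacterial controls (4.4 to 616), so its folds are imprecise. With all probe sets tested, a second RARA probe set rose by 3.33 ± 0.28 over both fusions (adjusted p = 0.00016) and 1 PML probe set by 3.17 ± 0.39 (adjusted p = 0.014). The other RARA and PML probe sets did not pass. Among them, 1 RARA probe set differed by 0.95 ± 0.33 (adjusted p = 1.0, signals of 14.5 to 65.9 in GFP, 108.1 to 182.3 in PRWT and 17.2 to 182.8 in PR2VR), another by -0.22 ± 0.26 and the PML probe set with the highest mean signal by 0.23 ± 0.23, and whether the plasmids hold their target sequence is not stated. In the fit of 1 probe set per gene, PML differed by 0.11 ± 0.28 in PRWT, and by -0.11 without number 2 of PRWT at 6 h.

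**Figure D1:**
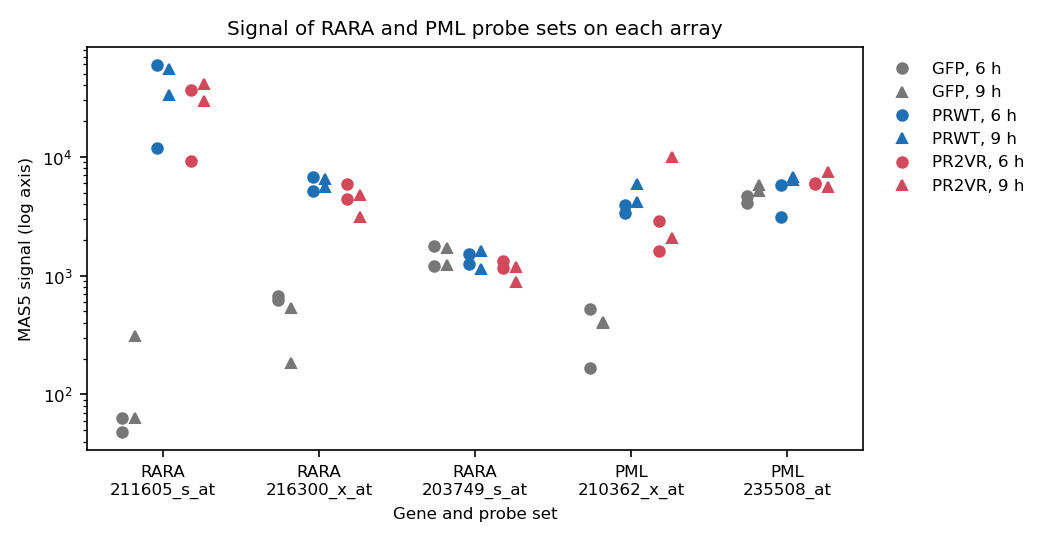
MAS5 signal (log axis) of 3 RARA and 2 PML probe sets, 1 point per array, coloured by construct and shaped by time after transfection. For the RARA probe set with the highest mean signal the GFP arrays lie between 48.2 and 309.2 and every fusion array lies at 9281.2 or above.

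The arrays of 9 h number 2 stood apart from the other 9. Their scores on the first principal component, which held 32.8% of the variance, were 59.8 to 77.7, against -36.4 to -7.31 for the other arrays. Their ratios of 3' to 5' signal, a measure of RNA integrity and labelling, were lower, at 2.21 to 2.75 for GAPDH against 3.82 to 12.9, and at 7.79 to 10.7 for actin against 12.5 to 58.2. A lower ratio means that less 5' signal was lost, so by this measure these were the better arrays. On all 12 arrays the 3' signal was the stronger, by at least 2.21 times for GAPDH and 7.79 times for actin. Their median signals were 387.6 to 435.8, against 238.8 to 292.4. All 3 constructs are in this set, so it is balanced over constructs and not over times. With this set omitted, the 9 h arrays had GAPDH ratios of 8.14 to 12.9 against 3.82 to 8.28 at 6 h, so this measure still tended to differ with time. Number 1 of PR2VR at 6 h stood apart as well, with a score of 65.2 on the second component (15.8% of the variance) against -41.1 to 14.8 on the other 11 arrays, and the lowest mean correlation with the others (0.901).

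**Figure D2:**
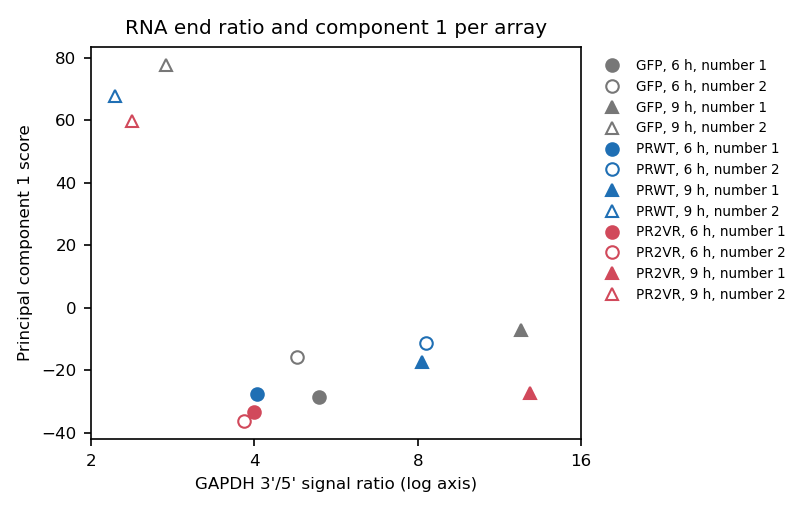
Score on the first principal component of the tested genes against the GAPDH ratio of 3' to 5' signal (log axis), 1 point per array, coloured by construct, with triangles for 9 h and open symbols for number 2. The 3 arrays of 9 h number 2 have ratios of 2.21 to 2.75 and scores of 59.8 to 77.7, and the other 9 have ratios of 3.82 to 12.9 and scores of at most -7.31.

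The first comparison asked what either form of the fusion changed relative to GFP, averaged over times. These values are from limma with the set as a block. ARID5B, a DNA-binding cofactor of histone demethylation, rose by 1.83 ± 0.21 (log2, SE, 12 arrays), the zinc finger factor KLF6 by 1.56 ± 0.19, SOX4, a factor of progenitor cells, by 1.50 ± 0.18, IRS2, an adaptor of insulin signalling, by 1.37 ± 0.16 and the scavenger receptor CD36 by 1.33 ± 0.18. CYTIP (1.36 ± 0.18), PELI2 (1.32 ± 0.18), LINC02806 (1.31 ± 0.23) and the glucose transporter gene SLC2A3 (1.22 ± 0.19) rose as well. Other transcripts fell. The changes were -1.98 ± 0.34 for AQP9, a glycerol and water channel, -1.89 ± 0.27 for IGFBP6, which binds insulin-like growth factors, -1.63 ± 0.23 for the amino acid oxidase IL4I1 and -1.60 ± 0.22 for IDO1, which degrades tryptophan. MS4A4A, a macrophage surface protein gene, changed by -1.53 ± 0.17, interferon lambda 1 (IFNL1) by -1.53 ± 0.25, the membrane-bending protein gene BIN1 by -1.47 ± 0.17, RAB20 by -1.40 ± 0.22 and the cell cycle inhibitor CDKN1A by -1.22 ± 0.15. The adjusted p of these genes lay between 0.010 and 0.048, and each moved the same way in 4 of 4 sets. In the fit without the block, the IFNL1 difference was -0.85 without number 2 of GFP at 6 h.

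IGHG1 (-2.15 ± 0.30) and SOCS1 (-1.84 ± 0.26) passed too but are uncertain, the former because immunoglobulin genes are near-identical and the latter because its other probe set went the opposite way. In all, 44 of 13959 genes passed with the block, 18 higher and 26 lower, and 44 of the 44 kept 1 direction over the 4 sets. The genes were picked on these same sets, so the shared direction is no separate support. Without the block only RARA passed (1 gene, 439 at an unadjusted p under 0.05 where chance gives 698), and the adjusted p of the genes above was 0.31 to 1.0. COL21A1, a collagen gene, did not pass by either fit (1.74 ± 0.31, adjusted p = 0.052 with the block). The count of 44 rests on the whole set of arrays: it was 1 without either GFP array of 6 h, without number 1 of GFP, PRWT or PR2VR at 9 h and without number 2 of PR2VR at 9 h. It was 2 without number 2 of GFP or of PRWT at 9 h, 10 and 22 without number 1 and number 2 of PRWT at 6 h, and 249 and 360 without number 1 and number 2 of PR2VR at 6 h. It was 1 without the variance trend, which alters no fold change, and 1 with the arrays of 9 h number 2 omitted together. In that omission the 44 genes had a median size of 1.30 (SE 0.28) where it had been 1.24 (SE 0.19), and residual degrees of freedom went from 4 to 2. All 44 kept their direction, which was bound to happen, since each had 1 direction over the 4 sets.

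Among the 28 gene lists, 4 shifted between fusion and GFP cells by camera. The interferon response list fell, with a median log2 difference of -0.40, 27 of its 28 members below 0 and an adjusted p of 3.1e-07. That call was lost with an estimated correlation (adjusted p = 0.64 with an estimated correlation), and the median was -0.18 (adjusted p = 0.10) without number 2 of GFP at 6 h. It was -0.61 without number 1 of GFP at 6 h and -0.23 without number 1 of PR2VR at 6 h, with the call kept. With the block, 1 member passed over all genes tested, the exonuclease ISG20 at -1.20 ± 0.20, and 5 passed adjusted over the list alone, which adds OAS1 (-0.71 ± 0.17), XAF1 (-0.91 ± 0.28), IFI6 and ISG15. Genes that retinoic acid induces fell, with a median of -0.47 and 10 of 10 members below 0 (adjusted p = 4e-04, and adjusted p = 0.074 with an estimated correlation). Their median was -0.29 (adjusted p = 0.0093) without number 2 of GFP at 9 h. In this list DHRS9, a retinol dehydrogenase gene, differed by -1.16 ± 0.24 and the surface enzyme CD38 by -0.89 ± 0.19. With the block 3 members passed adjusted over the list alone and 0 over all genes tested in limma, with 3 at an unadjusted p under 0.05. Without the filter on low signals 15 members were measured and the median was -0.30 (adjusted p = 0.066).

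The list of NF-kB targets and inflammatory cytokines fell (median -0.40, 16 of 21 members below 0, adjusted p = 0.0027, and adjusted p = 0.076 with an estimated correlation). TRAF1 differed by -1.22 ± 0.24, the adhesion molecule ICAM1 by -0.89 ± 0.19 and the NF-kB inhibitor NFKBIA by -0.80 ± 0.16, whereas PTGS2, an inducible enzyme of prostaglandin synthesis, differed by 1.45 ± 0.36. With the block, 8 members passed adjusted over the list alone, 2 higher and 6 lower, against 0 over all genes tested in limma and 9 at an unadjusted p under 0.05. The amino acid and ATF4 stress list rose (median 0.37, 14 of 16 members above 0, adjusted p = 1.6e-05, and adjusted p = 0.055 with an estimated correlation). Its members include TRIB3 (1.07 ± 0.20), the cystine transporter gene SLC7A11 (1.11 ± 0.29) and ATF4 itself (0.65 ± 0.13). With the block 6 members passed adjusted over the list alone, 5 higher and 1 lower, and 1 over all genes tested. The 4 sets gave medians of -0.56, -0.36, -0.39 and -0.32 for the interferon list and of 0.59, 0.24, 0.41 and 0.42 for the ATF4 list.

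The other 24 lists did not pass, with adjusted p of 0.13 or more. Myeloid lists had medians of -0.16 for transcription factors, -0.03 for monocyte and macrophage markers, -0.14 for granulocyte proteins and -0.01 for genes high in acute promyelocytic leukemia. Single members passed with the block: CEBPB, a factor of myeloid differentiation, fell (-1.07 ± 0.17, adjusted p = 0.034) and the Notch ligand JAG1, a gene high in acute promyelocytic leukemia, rose (1.00 ± 0.17, adjusted p = 0.048). Markers of other cells had medians of 0.29 for T cells, -0.15 for B cells, 0.11 for erythroid cells and megakaryocytes and -0.13 for epithelium and fibroblasts. Cell cycle and damage lists had medians of -0.05 for DNA replication, -0.12 for G2/M genes, -0.09 for p53 targets, -0.13 for apoptosis regulators, -0.11 for DNA repair and -0.03 for histones. The remaining medians were 0.12 for immediate early genes, 0.02 for heat shock proteins, -0.19 for chaperones of the endoplasmic reticulum, 0.05 for cholesterol synthesis, 0.05 for hypoxia and glycolysis and 0.02 for ribosomal proteins. They were 0.06 for components of PML bodies, 0.03 for retinoid receptors and corepressors, -0.05 for TGF-beta targets and -0.10 for the Notch pathway. The monocyte and histone lists had means above 0, at 0.02 and 0.08, and camera placed these and the promyelocytic leukemia list on the higher side despite their medians.

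The wild-type fusion alone, PRWT, was compared with GFP. RARA was the 1 gene that passed, without and with the block (288 and 760 genes at an unadjusted p under 0.05). Chance gives 698 in this and every other comparison. Other genes are given as values. The largest differences by the naming rule were 1.67 ± 0.37 for ARID5B, 1.41 ± 0.29 for CD36, 1.60 ± 0.37 for PTX3, a pattern recognition protein gene, and 1.72 ± 0.42 for COL21A1. On the lower side were BIN1 (-1.54 ± 0.29), CDKN1A (-1.28 ± 0.26), RAB20 (-1.47 ± 0.31), the kinase gene FGR (-1.55 ± 0.33) and IGFBP6 (-1.75 ± 0.40). Their adjusted p was 0.90 to 1.0, and 0.068 to 0.26 with the block, and each kept its direction in 4 of 4 sets.

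By camera, 3 lists shifted in PRWT against GFP. The ATF4 stress list rose (median 0.25, 14 of 16 above 0, adjusted p = 0.0018, and adjusted p = 0.14 with an estimated correlation). Retinoic acid targets fell (median -0.43, 9 of 10 below 0, adjusted p = 0.0069, and adjusted p = 0.17 with an estimated correlation), with DHRS9 at -1.25 ± 0.36, the 1 member that passed adjusted over the list alone. The interferon list fell (median -0.31, 25 of 28 below 0, adjusted p = 0.0027, and adjusted p = 0.92 with an estimated correlation). Over all genes tested 0 members of these lists passed in limma, with 3 ATF4, 1 retinoic acid and 1 interferon member at an unadjusted p under 0.05. With the block, 3, 1 and 2 members passed adjusted over the list alone. Each call was lost without some array. For the ATF4 list, leaving out number 2 of GFP or number 1 of PRWT at 9 h gave medians of 0.20 and 0.20 (adjusted p = 0.088 and 0.057). For the interferon list, the median was -0.02 without number 2 of GFP at 6 h, -0.01 without number 1 of PRWT at 6 h, -0.24 without number 2 of GFP at 9 h and -0.17 without number 1 of PRWT at 9 h, with adjusted p of 0.83, 0.81, 0.088 and 0.087. For retinoic acid targets those 4 omissions gave -0.36, -0.30, -0.20 and -0.23, and omitting number 2 of PRWT at 9 h gave -0.52, with adjusted p of 0.051, 0.32, 0.088, 0.057 and 0.058. Without the filter or with all probe sets the retinoic acid medians were -0.33 and -0.20 (adjusted p = 0.57 and 0.16). With the arrays of 9 h number 2 omitted together all 3 calls were lost, with medians of 0.16 for ATF4, -0.27 for retinoic acid and -0.31 for interferon (adjusted p = 0.075, 0.10 and 0.054). Calls were kept with larger medians for ATF4 without number 2 of PRWT at 6 h (0.47), number 1 of GFP at 9 h (0.42) and number 2 of PRWT at 9 h (0.39), and for interferon without number 1 of GFP (-0.52) and number 2 of PRWT (-0.50) at 6 h.

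The protease-resistant form, PR2VR, was compared with GFP in the same way. With the block, ARID5B rose by 1.99 ± 0.24, SOX4 by 1.82 ± 0.21, the ubiquitin ligase gene PELI2 by 1.76 ± 0.21, KLF6 by 1.67 ± 0.21, EVI2B by 1.52 ± 0.20, the pseudokinase gene TRIB1 by 1.51 ± 0.20 and IRS2 by 1.51 ± 0.19. LINC02806 (1.56 ± 0.26), CYTIP (1.44 ± 0.21) and the glucocorticoid-induced gene TSC22D3 (1.16 ± 0.17) rose too. AQP9 changed by -2.29 ± 0.39, IGFBP6 by -2.03 ± 0.31, IL4I1 by -2.02 ± 0.26, the chemokine CCL4 by -1.93 ± 0.33, IDO1 by -1.89 ± 0.25, MS4A4A by -1.75 ± 0.20, IFNL1 by -1.71 ± 0.28, the repressor ZBTB32 by -1.56 ± 0.24, BIN1 by -1.40 ± 0.20 and the kinase PIM1 by -1.24 ± 0.20. Their adjusted p lay between 0.015 and 0.046, with the same direction in 4 of 4 sets. IGHG1 (-2.16 ± 0.35) and SOCS1 (-1.87 ± 0.30) passed with the reservations given above. KDM7A, a histone demethylase gene (1.74 ± 0.31), and TNFRSF9 (-1.68 ± 0.32) did not pass (adjusted p = 0.053 and 0.062). In the fit without the block, CCL4 differed by -1.05 without number 1 of PR2VR at 6 h and IFNL1 by -1.03 without number 2 of GFP at 6 h.

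With the block 41 genes passed for PR2VR, 21 higher and 20 lower, and 30 of them were among the 44 called for both fusions together, 30 with the same direction. Without the block only RARA passed (1 gene, 551 at an unadjusted p under 0.05) and the adjusted p of the other genes was 0.52 to 1.0. The unblocked count was 9 without number 2 of PR2VR at 6 h, when ARID5B passed at 2.37 (adjusted p = 0.038). The blocked count was 1 when any GFP array or any array of 9 h was left out, 23 and 21 without number 1 and number 2 of PRWT at 6 h, and 416 and 739 without number 1 and number 2 of PR2VR at 6 h. With the arrays of 9 h number 2 omitted it was 1, with 41 of the 41 genes in the same direction and a median size of 1.50 (SE 0.33) where it had been 1.51 (SE 0.21). Without the variance trend it was 1.

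In PR2VR against GFP 6 lists shifted by camera. The NF-kB list fell (median -0.66, 18 of 21 below 0, adjusted p = 7.7e-05) and the ATF4 list rose (median 0.45, 13 of 16 above 0, adjusted p = 4.8e-05). Both held with an estimated correlation (adjusted p = 0.039 for each), but not when the block was added to that test (adjusted p = 0.15 and 0.19). NF-kB members include TRAF1 (-1.50 ± 0.28) and ICAM1 (-1.14 ± 0.22), and ATF4 members include TRIB3 (1.36 ± 0.23) and PSAT1, of serine synthesis (0.91 ± 0.26). Retinoic acid targets fell (median -0.51, 9 of 10 below 0, adjusted p = 0.00069, and adjusted p = 0.062 with an estimated correlation), with CD38 at -1.13 ± 0.22. The interferon list fell (median -0.57, 27 of 28 below 0, adjusted p = 1.9e-08, and adjusted p = 0.55 with an estimated correlation), and without number 1 of PR2VR at 6 h, the array that stood apart and had the lowest median log2 level of this list (12.30), its median was -0.18 (adjusted p = 0.24). It kept its call at -0.36 without number 2 of GFP at 6 h and at -0.96 without number 2 of PR2VR at 6 h. With the block, members that passed adjusted over the list alone numbered 10 for NF-kB, 8 for ATF4, 3 for retinoic acid and 13 for interferon, against 1, 1, 0 and 1 over all genes tested in limma, where 3 retinoic acid targets had an unadjusted p under 0.05.

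Immediate early genes, which respond within minutes to signals, rose in PR2VR (median 0.18, 12 of 19 above 0, adjusted p = 0.019, and adjusted p = 0.28 with an estimated correlation). With the block 5 passed adjusted over the list alone, among them DUSP1 (1.21 ± 0.23) and FOS (1.06 ± 0.27), and 1 over all genes tested, KLF6. Chaperones of the endoplasmic reticulum fell (median -0.29, 13 of 14 below 0, adjusted p = 0.019, and adjusted p = 0.16 with an estimated correlation), with PDIA4 at -0.65 ± 0.20. Of the chaperones 0 passed over the list alone or over all genes tested in limma, and with the block 1 had an unadjusted p under 0.05. The immediate early call was lost without number 1 of GFP at 6 h (median 0.21), number 2 of PR2VR at 6 h (0.10), number 2 of GFP at 9 h (0.15) and number 1 of PR2VR at 9 h (0.11), with adjusted p of 0.083, 0.25, 0.29 and 0.27, and the median was 0.32 with the call kept without number 1 of GFP at 9 h. The chaperone call was lost without number 2 of GFP at 6 h (-0.16), number 1 of PR2VR at 6 h (-0.19), number 1 of GFP at 9 h (-0.37) and number 2 of PR2VR at 9 h (-0.37), with adjusted p of 0.25, 0.24, 0.057 and 0.11. With the arrays of 9 h number 2 omitted, these medians were 0.23 and -0.20 (adjusted p = 0.062 for each).

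**Figure D3:**
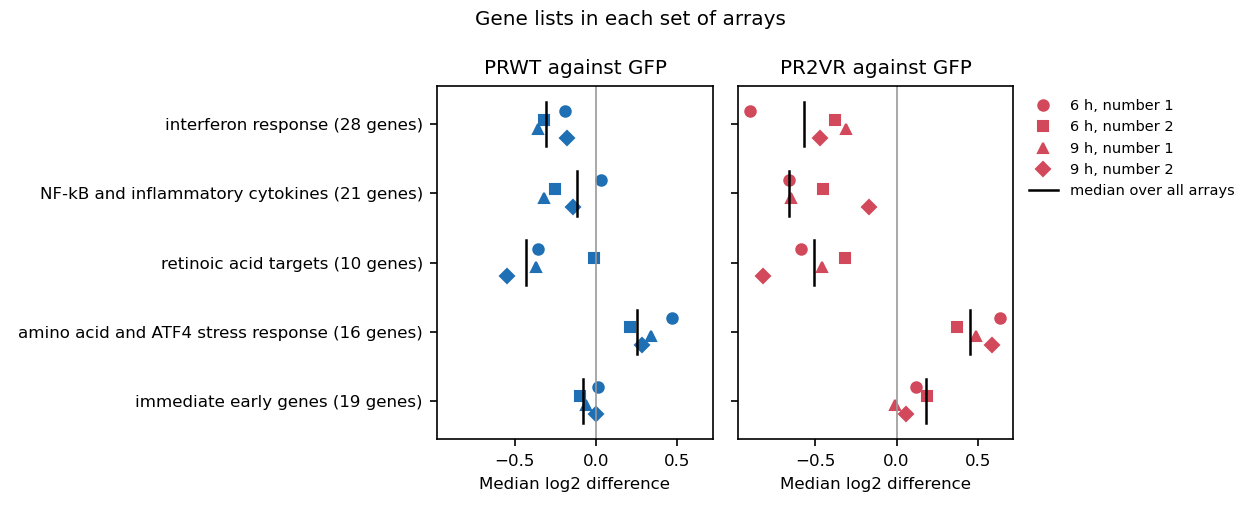
Median log2 difference of 5 gene lists in PRWT (left) and PR2VR (right) against GFP, with 1 point for each of the 4 sets of arrays (time and replicate number) and a black line for the median over all arrays. Interferon medians in PR2VR run from -0.90 to -0.31 and ATF4 medians from 0.37 to 0.64, and in PRWT the interferon medians run from -0.36 to -0.18.

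The comparison of PR2VR with PRWT asked what the second form changed beyond the first. In limma 0 genes passed, with 216 at an unadjusted p under 0.05, and with the block 0 passed with 957, where chance gives 698. Leaving out number 2 of PR2VR at 6 h gave 2 genes. The rule named GSDMB (1.69 ± 0.46), a pore-forming protein gene, RAD52 (1.36 ± 0.39) of DNA recombination, PRDM2 (1.10 ± 0.33), C2CD2L (1.10 ± 0.33) and MBLAC2 (0.91 ± 0.28) on the higher side. On the lower side were the folate receptor gene FOLR1 (-1.78 ± 0.46), METRN (-1.48 ± 0.43), the receptor kinase gene RET (-1.23 ± 0.36), DMBT1 (-1.21 ± 0.36) and MROH2B (-1.16 ± 0.36). All 10 had an adjusted p of 1.0, and 0.72 with the block. The median SE of 0.38 over genes leaves room for differences of moderate size.

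By camera the NF-kB list was lower in PR2VR than in PRWT (median -0.39, 19 of 21 below 0, adjusted p = 0.0016, and adjusted p = 0.13 with an estimated correlation). The 4 sets gave -0.48, -0.27, -0.27 and -0.21, and the chemokines CCL4 (-1.22 ± 0.33) and CXCL3 (-0.98 ± 0.34) were among the largest differences. With the block 2 members passed adjusted over the list alone, CCL4 and CCL2, and 0 over all genes tested in limma, with 5 at an unadjusted p under 0.05. The interferon list was lower too (median -0.31, 24 of 28 below 0, adjusted p = 0.0031, and adjusted p = 0.81 with an estimated correlation), with 0 members past the threshold in limma and 7 at an unadjusted p under 0.05 with the block. Without number 1 of PRWT at 6 h the NF-kB median was -0.13 (adjusted p = 0.027). Without number 1 of PR2VR at 6 h it was -0.29 (adjusted p = 0.19) and the interferon median turned to 0.05 (adjusted p = 0.36). The interferon call was also lost without number 2 of PRWT at 6 h (median -0.04, adjusted p = 0.82), number 2 of PRWT at 9 h (-0.18, 0.081) and number 2 of PR2VR at 9 h (-0.31, 0.16), with all arrays of 9 h number 2 omitted (-0.24, 0.28) and under quantile normalization (-0.20, 0.062). It was kept at -0.51 without number 1 of PRWT and at -0.68 without number 2 of PR2VR at 6 h. With the block 3 more lists passed: ribosomal proteins (median -0.17, 12 of 12 below 0, adjusted p = 0.0041, and 0.056 without), immediate early genes (0.16, 0.023 and 0.063) and chaperones of the endoplasmic reticulum (-0.19, 0.023 and 0.068). With the block and an estimated correlation their adjusted p was 0.69, 0.46 and 0.51. The other 23 lists did not pass by camera with or without the block.

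The effects of PRWT and PR2VR share their GFP arrays. At an unadjusted p under 0.05 with the block, 338 genes were higher in PRWT and 782 in PR2VR, 189 of them in both, where independent lists would give 18.9. Simulated unchanged groups with shared controls gave lists of 373 and 368 with 97.2 in both. Lists of the observed sizes from the same 20 simulations, a reference added after the counts were seen, had 138 in both (127 to 149). For lower genes the observed numbers were 422, 764 and 190, against 23.1 for independent lists, 96.2 for simulated lists of 364 and 370, and 161 (138 to 176) at the observed sizes. The simulation treats genes as independent, so its ranges are too narrow. In opposite directions went 1 gene, where the simulated unchanged groups with shared controls gave 4.65. Across the 13959 genes, which are not independent, the fold changes correlated at r = 0.567 where the simulation gave 0.50. Their covariance was 0.0841 against 0.0597, a difference of 0.0245. With separate GFP arrays for each fusion the covariance was 0.0406 and 0.0365 (r = 0.17 and 0.13), but such splits also pair arrays of different number.

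The comparison of 9 h with 6 h, over all constructs, was made with limma without a block. Interferon-inducible genes were among those that rose: IFI27 by 2.43 ± 0.34 (log2, SE, n = 6 arrays per time) and the GTPase gene GBP1 by 2.37 ± 0.35, with adjusted p of 0.030 and 0.033. ZBTB32, a transcriptional repressor of lymphocytes, rose by 2.73 ± 0.32 (adjusted p = 0.013), the decapping factor DCP1B by 1.66 ± 0.26, SAMSN1 by 1.55 ± 0.25 and the PML body component SP100 by 1.23 ± 0.20. INSIG1, which restrains sterol synthesis and is itself induced by low sterol, changed by -1.86 ± 0.29, the phosphodiesterase PDE9A by -1.69 ± 0.26, TSC22D3 by -1.51 ± 0.20, MYADM by -1.38 ± 0.20 and the decoy receptor TNFRSF10D by -1.36 ± 0.22. In all 11 genes passed, 6 higher and 5 lower (2105 at an unadjusted p under 0.05), and the median of all genes was 0.13. Quantile normalization gave 3 genes, 1 higher and 2 lower, with a median of all genes of 0.05.

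These counts rest on few independent samples, since arrays of 1 set deviate together and the arrays of 9 h number 2 stood apart, which makes the p-values of this comparison too small. With the set as a random block 0 genes passed in limma (766 at an unadjusted p under 0.05), and with the arrays of 9 h number 2 omitted 0 passed (719). The count was 0 without number 1 or number 2 of GFP at 6 h, without number 1 of PRWT or of PR2VR at 6 h, and without number 2 of GFP, PRWT or PR2VR at 9 h. It was 4 without number 2 of PRWT at 6 h, 53 without number 2 of PR2VR at 6 h, 5 without number 1 of GFP at 9 h, and 1 without number 1 of PRWT or of PR2VR at 9 h. It was 2 with all probe sets and 2 without the variance trend.

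Genes of cholesterol synthesis were lower at 9 h than at 6 h (median -0.80, 11 of 13 below 0, adjusted p = 2.6e-09 by camera). The list includes HMGCS1 (-1.77 ± 0.33) and IDI1 (-1.33 ± 0.29), enzymes of the mevalonate pathway. Adjusted over the list alone 9 members passed, and 1 over all genes tested, INSIG1. Against the mean of all 6 h arrays the median was -0.69 for number 1 of 9 h and -0.90 for number 2 of 9 h. Both values share that baseline and are not separate comparisons. No list over time was tested with the set as a random block. Arrays of 1 set deviate together, so the p-values of all lists over time are too small, as for the genes. Immediate early genes were lower (median -0.53, 15 of 19 below 0, adjusted p = 8.1e-07), with FOSB at -3.17 ± 0.70, JUND at -1.33 ± 0.23 and EGR3 at -1.19 ± 0.27. Of these 7 passed adjusted over the list alone and 0 over all genes tested in limma, with 9 at an unadjusted p under 0.05. The ATF4 list was lower (median -0.40, 15 of 16 below 0, adjusted p = 6.7e-05), with ATF4 at -0.86 ± 0.19, the 1 member that passed adjusted over the list alone, against 0 over all genes tested and 3 at an unadjusted p under 0.05. All 3 lists held with an estimated correlation (adjusted p = 0.036 for each), although the ATF4 call was lost in that test with the replicate number as a block (adjusted p = 0.066), which pairs arrays across times weakly at most. By camera all 3 kept their calls when any 1 array was left out, with immediate early medians of -0.34 without number 2 of GFP and -0.35 without number 2 of PR2VR at 9 h. With the arrays of 9 h number 2 omitted the 3 medians were -0.69, -0.26 and -0.30, with the calls kept.

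The interferon list was higher at 9 h (median 0.44, 23 of 28 above 0, adjusted p = 6.7e-05, and adjusted p = 0.62 with an estimated correlation). It includes XAF1 (1.79 ± 0.32), OAS3 (1.74 ± 0.34) and the RNA sensor RIGI (1.47 ± 0.29). Adjusted over the list alone 10 members passed, and 1 over all genes tested, IFI27. Without number 1 of PR2VR at 6 h the median was 0.19 (adjusted p = 0.087), and without number 2 of PR2VR at 6 h it was 0.73. The hypoxia and glycolysis list was lower (median -0.42, 15 of 19 below 0, adjusted p = 0.00018, and adjusted p = 0.24 with an estimated correlation), with ALDOC at -0.81 ± 0.23 and a median of -0.25 (adjusted p = 0.0020) without number 1 of PR2VR at 6 h. In limma 0 of its members passed by either adjustment, with 5 at an unadjusted p under 0.05. Ribosomal protein genes were lower (median -0.33, 12 of 12 below 0, adjusted p = 2e-04, and adjusted p = 0.56 with an estimated correlation), but their median was -0.02 (adjusted p = 0.64) under quantile normalization. Of these 0 passed by either adjustment in limma, with 1 at an unadjusted p under 0.05. With the arrays of 9 h number 2 omitted the interferon, hypoxia and ribosomal medians were 0.40, -0.21 and -0.11, with the calls kept.

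Within single time points RARA was the 1 gene that passed in each comparison with GFP. It rose by 7.82 ± 0.77 at 6 h and 7.62 ± 0.77 at 9 h in PRWT (adjusted p = 0.0020 and 0.0027), and by 7.30 ± 0.77 and 7.34 ± 0.77 in PR2VR (adjusted p = 0.0044 and 0.0041, n = 2 arrays per group). The PRWT count at 6 h was 0 without either GFP array or number 1 of PRWT. The PR2VR count at 6 h was 0 without either GFP array or number 1 of PR2VR, and 35 without number 2 of PR2VR. At 9 h the PR2VR count was 0 without number 1 of GFP and without either PR2VR array. At both times 0 genes passed in limma between PR2VR and PRWT, with 301 at 6 h and 103 at 9 h at an unadjusted p under 0.05, and the count at 6 h was 35 without number 2 of PR2VR. The test of whether the effect of PRWT or of PR2VR differed between times gave 0 genes each, with 140 and 101 at an unadjusted p under 0.05.

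Lists were tested within single time points too, by camera, and 0 of them passed there with an estimated correlation (smallest adjusted p = 0.090). In PR2VR against GFP 5 lists shifted at 6 h: interferon (median -0.75, adjusted p = 5.8e-07), NF-kB (-0.67, 0.0015), immediate early genes (0.36, 0.026), ATF4 (0.47, 0.0083) and retinoic acid targets (-0.52, 0.027). At 9 h 6 shifted: interferon (-0.36, 0.00029), NF-kB (-0.42, 0.0043), chaperones of the endoplasmic reticulum (-0.29, 0.017), ATF4 (0.54, 0.00029), retinoic acid targets (-0.61, 0.0034) and cholesterol synthesis (0.12, 0.035). In PRWT against GFP 2 shifted at 6 h, ATF4 (0.39, 0.034, and 0.057 with the block) and the erythroid and megakaryocyte markers (0.76, 0.034, and 0.060 with the block), and the block added interferon (-0.30, 0.0034) and G2/M genes (-0.24, 0.038). At 9 h 3 shifted, interferon (-0.33, 0.037), retinoic acid targets (-0.62, 0.037) and ATF4 (0.30, 0.037, and 0.075 with the block). Between PR2VR and PRWT 2 shifted at 6 h, interferon (-0.46, 0.013) and NF-kB (-0.38, 0.015). At 9 h 0 of the 28 passed, and with the block NF-kB (-0.27, 0.013), chaperones (-0.30, 0.0064) and ribosomal proteins (-0.25, 0.0064) did. Omissions of single arrays were not run for these lists.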

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

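The test of RNA integrity for the arrays of 9 h number 2, the test of fusion RNA in PR2VR and the splits that keep the set of 9 h number 2 in place were chosen after the values they use had been seen, and so were the omission of that set and the fits with the set as a random block. The overlap lists of the observed sizes were added afterwards too. No outcome was written down for the division of the time splits by the arrays of 9 h number 2, nor for the medians of the NF-kB list in single sets. The other tests of explanations were written down before their results.

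The erythroid and megakaryocyte list, of which 4 genes were measured, had a PRWT effect that differed between times, with a median of -1.37 for the effect at 9 h minus that at 6 h (3 of 4 below 0, camera adjusted p = 0.032, and adjusted p = 0.46 with an estimated correlation, or 0.056 with the block).

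The first pattern is the separate position of the arrays of 9 h number 2. Scaling by the authors was tested by quantile normalization, which left a gap of 56.4 on the first component where it had been 67.1, a ratio of 0.841, and this argues against a difference in scale as the whole of it. A difference in RNA integrity or labelling may account for it, since 3 of the 3 arrays lie outside the range of the other 9 in the 3' to 5' ratios of both GAPDH and actin. A different transfection or culture stays open, as no label bears on it and no biological explanation was tested.

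The second pattern is the 44 genes called with the block between fusion and GFP cells. Chance is argued against for that count, since 1 of the 81 ways to place the GFP role within sets gave as many, with 44 for the real one and 1 as the highest of the others. No smaller share was possible, and the test covers the count and no single gene. The count also rests on the block, the variance trend and the whole set of arrays, as given above. RNA integrity within sets was tested with the GAPDH ratio as a covariate, and the median ratio of new to old fold changes was 0.965 (range 0.891 to 1.09). This cannot decide on integrity. The log2 GAPDH ratio of fusion minus GFP arrays was -0.39, 0.23, -0.28 and -0.26 in the 4 sets, so it was partly balanced. The genes were picked for a small residual spread, so their fold changes had little room to move. The median size went from 1.24 (SE 0.19) to 1.23 (SE 0.20), and the number of calls went from 44 to 1; the loss of 1 of the 4 residual degrees of freedom and the rise in SE were not separated as the reason. The count needed the labels of the other sets beside those of 9 h number 2. Of the 27 splits that keep the arrays of 9 h number 2 in place, 1, the real one, gave as many genes, and the highest other gave 0. These splits were chosen after the data were seen. A call needs agreement between sets, so they do not measure how much of the differences came from that set. The test set in advance for the set of 9 h number 2 as the origin was undecided. Genes picked as largest in that set had medians of 0.09, 0.13 and 0.18 in the other sets, between its bounds. An effect of the fusion on the 44 is a candidate explanation, beside a difference in procedure that the titles leave open.

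The third pattern is the lower NF-kB list in PR2VR than in PRWT. A sole origin in number 1 of PR2VR at 6 h is argued against, as the median was -0.29 without that array and -0.27, -0.27 and -0.21 in the other 3 sets, although the adjusted p was then 0.19 with 1 array fewer. Without number 1 of PRWT at 6 h the median was -0.13, which lies between the bounds set in advance for the other array and leaves this array undecided. The same 3 sets lack it too and had medians below 0, but no test of it was written down. More fusion RNA in PR2VR was not seen: RARA was lower in 4 of 4 sets (mean -0.40, SE 0.11, exact sign-flip p = 0.125, the smallest that 4 sets allow). Its second probe set was lower too (-0.42, SE 0.21), and the PML probe set that rose was lower in 3 of 4 (-0.44, SE 0.45). The sign-flip test was chosen after the values were seen and could not fall under 0.05, so it does not decide the question. The resistance of PR2VR to proteases is the explanation that the design names and it may apply, but no value here tests it.

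Other splits of the arrays into groups of the same size gave these counts. For both fusions against GFP without the block, 5 of 100 splits gave at least the real count of 1, with 23 as the highest other, so the size of the count does not exclude chance. The gene itself is the transfected RARA, with signals of at most 309.2 on GFP arrays and at least 9281.2 on fusion arrays, and it passed in 12 of 12 omissions of 1 array. For PRWT 2 of 18 splits gave at least the real count (real 1, highest other 233), for PR2VR 1 of 18 (real 1, highest other 0) and for PR2VR with the block 1 of 8 (real 41, highest other 1). These are too few splits for a share under 0.05. For PR2VR against PRWT the real count was 0, so 18 of 18 splits were bound to reach it (highest other 1) and nothing was tested. The split with 233 genes parts the arrays by replicate number at both times, which points to a structure of the samples, and with the block the PRWT count is 1. For 9 h against 6 h 2 of 100 splits gave at least the real 11, a share that excludes chance only if arrays were independent, and the highest other, 423, follows the replicate number at both times. Of the 100 splits, 26 keep the arrays of 9 h number 2 on 1 side and 2 of these reach the real count, while the highest count among the 74 that part them was 0, so the structure of that set bears on this count.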

How the results depend on the processing

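The omission of the arrays of 9 h number 2, the random block and the alternatives applied to the fit with the block and to the lists were chosen after the data were seen. The others were planned. For the counts of genes, an offset of 1 and no filter kept all 13 within 1.5 times. The direction of every named gene held with an offset of 1 and after quantile normalization. Other alternatives that use all 12 arrays take the same probe set and leave its fold change as it is, so they could not alter a direction. The cause of each shift below was not tested.

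Both fusions against GFP gave 44 genes with the replicate block (main 1), 38 with the random block (consensus correlation 0.41) and 5 with all probe sets. PRWT against GFP gave 2 with the random block and 3 with all probe sets. PR2VR against GFP gave 41 with the block, 38 with the random block and 3 with all probe sets. The blocked counts of 44 and 41 were 1 and 1 without the variance trend, 1 and 1 with the arrays of 9 h number 2 omitted, 38 and 33 with an offset of 1 (38 and 33 shared), 53 and 47 after quantile normalization (43 and 41 shared) and 40 and 43 without the filter (39 and 38 shared). For 9 h against 6 h the count of 11 was 3 after quantile normalization, 2 with all probe sets, 2 without the trend, 0 with the random block and 0 with the arrays of 9 h number 2 omitted. Replicate numbers pair arrays across times weakly at most (r from -0.022 to 0.19), so the 164 genes with the number as a block there are not given as a result. An effect of the number shared by both times is not excluded. PRWT at 9 h gave 2 with all probe sets, and with only the arrays compared PRWT at 9 h gave 0 and PR2VR at 9 h gave 0 (185 and 317 at an unadjusted p under 0.05). For lists, the block added 3 camera calls for PR2VR against PRWT and ended that of the erythroid list (0.056) and the estimated-correlation calls of NF-kB and ATF4 in PR2VR (0.15 and 0.19). Its effects on lists within single time points are given with them. Over time it added DNA replication by camera (0.043) and ended ATF4 with an estimated correlation (0.066). In the comparisons of constructs averaged over times it changed no other count, and no other list call by these 2 tests.

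Leaving out 1 array in turn gave 1 to 360 for the blocked count of both fusions, 1 to 739 for that of PR2VR, 0 to 53 for 9 h against 6 h, 1 to 1 for both fusions, 1 to 1 for PRWT, 1 to 9 for PR2VR and 0 to 2 for PR2VR against PRWT. By time it gave 0 to 1 (6 h) and 1 to 1 (9 h) for PRWT, 0 to 35 and 0 to 1 for PR2VR, 0 to 35 and 0 to 0 for PR2VR against PRWT, and 0 to 0 for both tests of a difference between times. Values that changed sign were PML in PRWT (-0.11 without number 2 of PRWT at 6 h, 0.33 at the highest), RARA in PR2VR against PRWT (0.17 without number 1 of PRWT at 6 h and 0.10 without number 2 of PR2VR at 6 h, -0.97 at the lowest) and the interferon list there (0.05 without number 1 of PR2VR at 6 h, -0.68 at the lowest).

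Of 21 list calls 5 held with an estimated correlation and 8 with fry, 21 held with the block, 21 with an offset of 1, 19 without the filter, 20 with all probe sets, 19 after quantile normalization and 15 with the arrays of 9 h number 2 omitted, where the 3 lists of PRWT, the immediate early and chaperone lists of PR2VR and the interferon list of PR2VR against PRWT were lost. Genes near the signal of the bacterial controls (median 37.7) give folds that are too small, since 62.5 is added before the log.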

Other observations

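The lists and genes here were chosen after their values had been seen, from lists fixed before. Several groups that were not called over time had medians above that of all genes (0.13). Monocyte and macrophage markers had a median of 0.35 at 9 h against 6 h, with 16 of 18 above 0 (camera adjusted p = 0.058), and CD36, a scavenger receptor, differed by 1.27 ± 0.24 (adjusted p = 0.084). Their median log2 level was 9.50 to 9.95 at 6 h, 10.05 to 10.31 at 9 h number 1 and 10.11 to 10.48 at 9 h number 2. The arrays of 9 h number 2 were also higher in B cell markers (10.36 to 10.57 against 8.14 to 9.60 on the others) and in epithelial and fibroblast markers (9.10 to 9.56 against 8.25 to 9.00). The median signal of all probe sets was higher on these arrays too (387.6 to 435.8 against 238.8 to 292.4). Marker levels were not adjusted for this, so they do not show a difference in cell type. Retinoic acid targets had a median of 0.60 with 8 of 10 above 0 (adjusted p = 0.16), DHRS9 among them at 1.08 ± 0.30 (adjusted p = 0.19). DNA replication genes had a median of 0.29 with 20 of 23 above 0 (adjusted p = 0.078).

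Some lists lay on opposite sides in the 2 kinds of comparison. The ATF4 list had a median of 0.37 in fusion cells against GFP and of -0.40 at 9 h against 6 h, and the interferon list had -0.40 and 0.44. ZBTB32 was lower in PR2VR cells (-1.56 ± 0.24 with the block) and higher at 9 h (2.73 ± 0.32), and TSC22D3 was higher in PR2VR cells (1.16 ± 0.17 with the block) and lower at 9 h (-1.51 ± 0.20). These comparisons rest on the same 12 arrays and the contrast between them was not tested.

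The differences of fusion from GFP cells were also set against each other between the 4 sets of arrays. Across 13959 genes, which are not independent replicates, they correlated at r = 0.24 between the 2 sets of 9 h and at r = 0.032 between the 2 sets of 6 h, and at r = 0.025 to 0.18 between a set of 6 h and a set of 9 h.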
